A study of Mus musculus with 7 samples.

How the data were processed

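RNA from sorted tumour cells was measured on 7 Affymetrix mouse expression arrays, 2 from tumours with wild-type Ptprd, 2 from heterozygous tumours and 3 from tumours without functional Ptprd, called null here. Per the labels' protocols, tumours were taken at symptoms or at 12 weeks, dissected under a fluorescence microscope and digested with papain, and living cells that carried the green fluorescent marker were sorted into Trizol. Labelled RNA was made from 75 ng of total RNA with a kit that primes at the 3' end of transcripts, so the probe sets measure mainly the 3' part of each gene. The labels call the arrays of a group biological replicates and do not say whether each holds the tumour of a single mouse.

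The deposited values are log2 expression values, and the submitters' processing notes name RMA and Partek 6.6. RMA corrects for background, sets the arrays to a common distribution and summarises the probes of a probe set. Because of the common distribution, a shift of all genes in one direction cannot be seen. Scanner files were not used here. The table held 22690 probe sets, of which 64 were Affymetrix controls that served only for array quality. No pair of arrays held identical values.

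Probe sets were named from the platform's annotation. Of the 22626 probe sets other than controls, 20380 named 1 gene, 691 named several genes and 1555 were unnamed here. Symbols were compared with RefSeq genes of the assembly GRCm38.p6. This changed 0 symbols and left 29 single-gene probe sets without a match. Each of the 12393 named genes was represented by its probe set with the highest mean over the 7 arrays. A gene was tested if that probe set lay above the 30th percentile of the array on at least 2 arrays, which left 9243 genes and removed 3150.

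A linear model with a mean for each genotype was fitted to all 7 arrays with limma 3.58.1 in R 4.3.3, so that the groups shared an estimate of the spread with 4 residual degrees of freedom. Moderated tests were made for each pair of genotypes, for the mean of heterozygous and null against wild type, for any difference among the 3 genotypes (F test) and for a slope on the number of wild-type alleles. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. All tests were two-sided. The p-values measure the spread between these arrays, and the number of arrays limits the precision. The fit was tested on simulated data with 200 changed genes among 9243. For heterozygous against wild type it recovered 10.5% of genes changed by 0.5 on the log2 scale, 79.1% of those changed by 1 and 98.5% of those changed by 2. For null against wild type the shares were 16.4%, 91.0% and 98.5%, and for null against heterozygous 14.9%, 89.6% and 100%. The simulated spread was independent between genes and between arrays, and the adjustment becomes stricter where fewer genes change. The shares therefore do not tell how many changes were missed in a comparison with few or 0 calls.

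Before the data were examined, 32 gene lists were fixed, which covered STAT3 and receptor signalling, glioma classes, cell states, cell cycle, stress and markers of other cell types. Lists were tested with camera at a preset correlation of 0.01 between genes, with adjustment over the lists of a comparison. Members of a list are called measured where they are among the genes tested, so members below the filter on dim genes are not counted. Lists with fewer than 5 measured members were described without a set test. Camera with an estimated correlation and fry were alternatives. In a simulation with genes drawn independently of each other, the shifted list was called and 0 of 30 unchanged lists were called. This does not show how often lists of correlated genes are called by chance. The correlation estimated from the data was 0.954 for the G2/M list, 0.0587 for the mesenchymal list and -0.0451 for chemokines. The value for chemokines lies below the preset one. Even so, their unadjusted camera p in heterozygous against wild type went from 0.000499 to 0.0199 with the estimated correlation. The 2 forms of camera therefore differ in more than the correlation, and a lost call does not by itself show correlated genes.

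The genes named in the text follow a rule fixed at the same time. It takes Ptprd, the 10 largest rises and the 10 largest falls per pair of genotypes among genes past the threshold whose groups did not overlap (filled up with the genes of smallest p where fewer passed), up to 4 members of smallest p per gene list, a few genes of the STAT3, chemokine and macrophage lists chosen by name, and the 5 genes of smallest p in the F test and in the slope. Predicted genes without a proper name were skipped. Genes named outside the rule are marked as such. Among the named genes past the threshold that had several probe sets, these differed in sign for Sh3rf1 and Higd1a in heterozygous against wild type and for Ptprk and Higd1a in null against heterozygous.

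The alternatives were repeated quantile normalization, median centring, no filter or a filter at the 50th percentile, the mean of a gene's probe sets, every probe set by itself, probe sets with shared or cross-hybridising probes left out, robust moderation with a trend, no moderation, array weights, only the groups compared, the replicate number as a block, sex-linked and immunoglobulin genes left out, the 3' minus 5' difference of the control transcripts as a covariate, and each array left out in turn. A fit without the arrays that carry both Xist and Y-linked transcripts and a fit with the level of Y-linked genes as a covariate were added after the data were seen. Covariances and correlations between 2 comparisons that share the wild-type or the heterozygous arrays were set beside the mean of 100 simulations of unchanged groups.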

Results

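Gliomas had been induced in mice by cerebral injection, on postnatal days 1 to 3, of RCAS-PDGFB-GFP, an avian retroviral vector that carries platelet-derived growth factor B and a green fluorescent marker and infects only cells that express its receptor tv-A, here from the Nestin promoter. All mice lacked p16, a cell cycle inhibitor of the Cdkn2a locus, and were of mixed C57/BL6 and FVB/N background. They differed in Ptprd, which encodes a receptor-type protein tyrosine phosphatase. The 7 arrays comprised 2 wild-type, 2 heterozygous and 3 null samples of sorted tumour cells. The design asks how glioma cells differ after loss of 1 or both alleles of Ptprd. Median log2 values of the arrays lay between 6.62 and 6.71.

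The heterozygous arrays stood apart from the other 5. Across probe sets, which are not independent replicates, wild-type and null arrays correlated with each other at 0.990 to 0.995 and arrays within a group at 0.991 to 0.993. Each wild-type and null array correlated best with an array of the other of these genotypes. Wild type replicate 1 and null replicate 2 were closest to each other (0.995), as were wild type replicate 2 and null replicate 3 (0.993). Heterozygous arrays correlated with wild-type arrays at 0.976 to 0.985 and with null arrays at 0.976 to 0.987. The first principal component held 58.4% of the variance and placed the heterozygous arrays at 39.4 and 27.1, and the others between -19.6 and -5.64. Sex-linked transcripts differed within every group. Xist, the RNA of the inactive X chromosome, was high without Y-linked transcripts in wild type replicate 2, heterozygous replicate 2 and null replicate 3. Y-linked transcripts were high without Xist in wild type replicate 1 and null replicate 2. The pairs of wild-type and null arrays closest to each other thus carried the same kind of sex-linked transcript, and the reason was not tested. Heterozygous replicate 1 and null replicate 1 carried both.

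**Figure D1:**
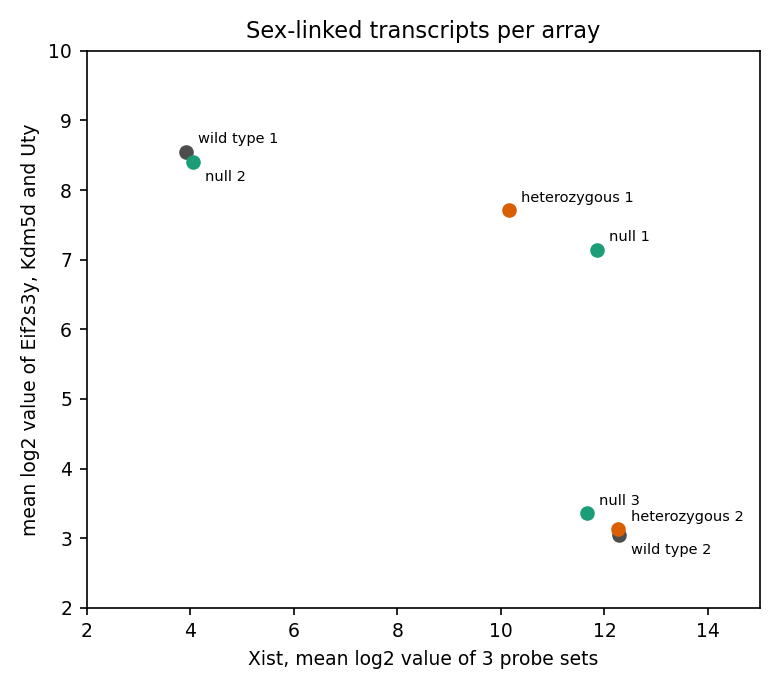
Mean log2 value of 3 Xist probe sets (x axis) against the mean log2 value of Eif2s3y, Kdm5d and Uty (y axis), 1 point per array, coloured by genotype. Heterozygous replicate 1 (10.2 and 7.71) and null replicate 1 (11.9 and 7.14) are high on both axes.

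Ptprd RNA was lower in both deficient groups than in wild type. The level of its brightest probe set was 10.87 ± 0.02 (log2, SD, n = 2) in wild type, 9.50 ± 0.11 (n = 2) in heterozygous and 9.50 ± 0.50 (n = 3) in null tumour cells. Heterozygous cells were 2.59-fold lower than wild type (log2 difference -1.37 ± 0.28, SE, adjusted p = 0.0311). In null cells the log2 difference was -1.37 ± 0.26, with an unadjusted limma p of 0.00106 that did not pass the adjustment (0.883). Null and heterozygous cells differed by 0.00 (log2, 95% interval -0.60 to 0.61 in the fit of every probe set). The 2 other probe sets of Ptprd differed from wild type by -1.52 and -1.38 in heterozygous and by -1.23 and -1.30 in null cells. All 5 deficient arrays were below both wild-type arrays, and an exact two-sided permutation test of wild type against deficient arrays gave p = 0.0476, the smallest that 21 splits allow. Ptprd RNA therefore separated the wild-type label from the deficient labels and did not separate heterozygous from null. It is not known here whether the probe sets lie in the part of the transcript removed by the targeting, and probe sets outside that part do not check the labels. Leaving out wild type replicate 1 or 2, heterozygous replicate 1 or 2, or null replicate 1 ended the call in heterozygous cells (adjusted p between 0.0522 and 0.162, log2 differences between -1.45 and -1.30). It also ended with an unmoderated model (0.131) and without both arrays that carried Xist and Y-linked transcripts (0.226, a setting chosen after the data were seen).

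**Figure D2:**
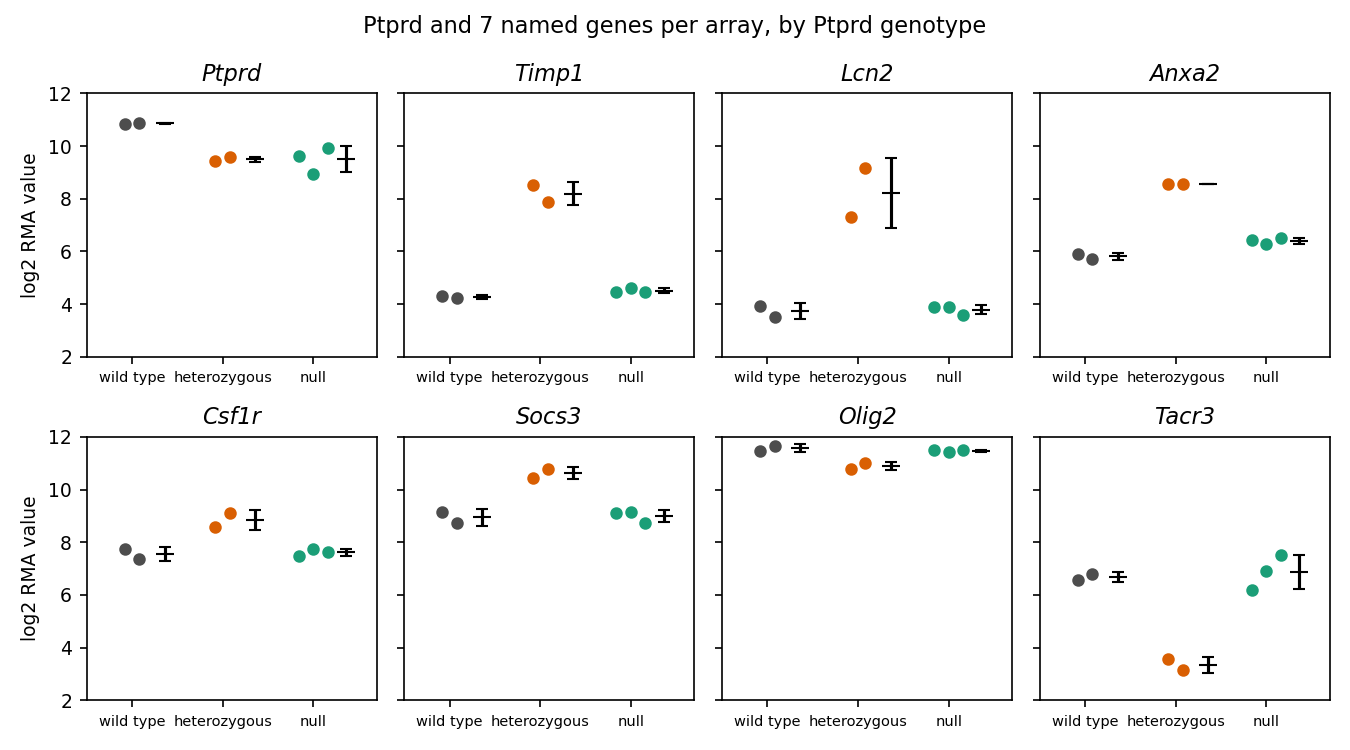
Log2 RMA values of Ptprd and 7 named genes (y axis) in the wild-type, heterozygous and null arrays (x axis), with 1 point per array and the mean ± SD beside the points. Ptprd lies near 10.87 in wild type and at 9.50 in both deficient groups, whereas Timp1 is at 8.20 in heterozygous cells and at 4.26 and 4.51 in wild-type and null cells.

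This comparison asks how glioma cells differ after loss of 1 allele. Among the genes that rose in heterozygous against wild-type cells, Cd44, the hyaluronan receptor, rose by 5.08 ± 0.95 (log2 difference, SE, adjusted p = 0.0244), Lcn2, an iron-binding acute-phase protein, by 4.50 ± 0.53 (adjusted p = 0.00774), and Aldh1a3, a retinaldehyde dehydrogenase, by 4.25 ± 0.37 (adjusted p = 0.00377). Timp1, an inhibitor of metalloproteases, rose 15.3-fold (log2 difference 3.93 ± 0.20, adjusted p = 0.000895). The wild-type mean of Timp1 lay below the 30th percentile of both wild-type arrays (4.84 and 4.82). Its fold is therefore taken against a dim level, and its exact size is uncertain. The smallest differences among the other probe sets of these genes were 2.25 for Cd44 and 1.04 for Aldh1a3. Lgals3, which encodes galectin-3, rose by 3.59 and Osmr, the receptor subunit for oncostatin M, by 3.23. The other large rises were Clca3a1 (4.94), Moxd1 (4.27), the matrix protein Mgp (3.24) and Npl (3.11). The largest falls were smaller than the largest rises. The protocadherin Pcdhb9 fell by 3.48 ± 0.45 (adjusted p = 0.00974), the neurokinin receptor Tacr3 by 3.34 ± 0.38 (adjusted p = 0.00749) and the homeobox gene Meox1 by 2.43. Tenm1, Aldh1a1, Rit2, the contactin Cntn3, the adenylate cyclase Adcy8, the neuregulin Nrg3 and Olfm3 fell by between 1.82 and 2.38. In total, 938 of 9243 genes passed the threshold, 388 higher and 550 lower, and 184 of the higher and 122 of the lower genes differed over 2-fold. The 2 groups did not overlap for 61.3% of genes, against 33.3% by chance. The excess of lower genes depended on the setting. The count was 196 without wild type replicate 1 (103 higher and 93 lower), 33 without wild type replicate 2 (23 and 10), 165 without heterozygous replicate 1 (99 and 66), 97 without moderation (46 and 51), 172 with these groups alone (99 and 73) and 372 with the 3' minus 5' covariate (186 and 186). It was 0 (1802 at an unadjusted limma p under 0.05) without the 2 arrays that carried both Xist and Y-linked transcripts, a setting chosen after the data were seen that leaves 1 heterozygous array.

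Genes of the mesenchymal glioma class and STAT3 targets were shifted upwards, in the same arrays in which macrophage markers, described next, were higher. Of 22 mesenchymal genes measured, 12 rose and 0 fell (14 and 1 adjusted over the list alone), with a median log2 difference of 1.54 (0.63 without a filter on dim genes). Camera gave adjusted p = 7.763e-10, or 0.201 with an estimated correlation. Anxa2, an annexin of the cell membrane, rose by 2.74 ± 0.12 (SE, adjusted p = 0.00078), and Timp1, Anxa1 (1.99) and Lgals3 rose with it. Of the 22 genes, 10 also stand in other lists, Timp1 and Cd44 among them. Of 27 STAT3 targets and acute-phase genes, 9 rose and 1 fell (13 and 1 adjusted over the list alone), with camera's adjusted p = 1.144e-07, or 0.201 with an estimated correlation. Their median of 0.70 was 0.46 without heterozygous replicate 2 and 1.12 with the filter at the 50th percentile. The genes included Timp1, Lcn2, the transcription factors Myc (1.55) and Junb (1.01), and Socs3, the feedback inhibitor of STAT3 signalling (1.69 ± 0.21, adjusted p = 0.00934). Stat3 itself differed by 0.42 (adjusted p = 0.156). Of 23 JAK-STAT pathway components, 2 rose (Socs3, Osmr) and 4 fell, Lifr by 1.47 and Pias1 by 0.72 among them, with other probe sets at -0.02 and -0.29 (2 and 4 over the list alone), and the list was not called (adjusted p = 0.588).

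Markers of microglia and macrophages, cells other than the sorted tumour cells, rose as a group. Of 33 listed, 24 were measured, of which 18 rose and 0 fell (21 and 0 adjusted over the list alone), with a median of 1.31. Camera gave adjusted p = 1.872e-14, or 0.201 with an estimated correlation. Ptprc, the leukocyte antigen CD45, rose by 1.40 ± 0.14 (SE, adjusted p = 0.00491), Cd53 by 1.72, Cd68 by 0.93, Cx3cr1 by 0.78 and Csf1r, the receptor for colony-stimulating factor 1, by 1.29 (0.57 in another probe set). Of 17 chemokines, 3 rose and 0 fell (8 and 1 over the list alone): Ccl12 by 2.25, Ccl2 by 1.05, both attractants of monocytes, and Cxcl14 by 0.89 (0.14 in another probe set), while Ccl6 was at 1.00 (adjusted p = 0.0527). Camera gave adjusted p = 0.00133 for chemokines, or 0.201 with an estimated correlation. Of 18 alternatively activated macrophage genes listed, only 5 were measured. They were not called (0 of 5 past the threshold and 0 over the list alone, camera's adjusted p = 0.588). Aif1, Mrc1 and Arg1, chosen by name, are on the array but lay below the filter and were not tested. Of 18 classically activated macrophage genes listed, 4 were measured, of which 0 passed limma's threshold and 0 passed over the list alone. These counts say nothing about the members that were not measured.

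Further lists were shifted upwards in the same arrays in which macrophage markers were higher. Of 24 interferon response genes, 3 rose and 1 fell (11 and 1 over the list alone). The risen genes were Ifitm3 (3.02), Gbp2 (2.68) and Mx2 (0.79), and the fallen gene was Ifit2 (-0.50). Of 14 antigen presentation genes, 1 rose, H2-Ab1 (1.99, adjusted p = 0.0478, and less in another probe set), and 0 passed over the list alone. Camera's adjusted p was 1.129e-07 and 0.00133, and 0.372 and 0.514 with an estimated correlation. The interferon median of 1.31 was 0.81 without wild type replicate 1, 0.70 without heterozygous replicate 1 and 1.97 without heterozygous replicate 2. The antigen presentation median of 0.97 was 1.45 without wild type replicate 2 and higher still without heterozygous replicate 2, and the call ended without wild type replicate 1 (median 0.56, adjusted p = 0.0656) and without heterozygous replicate 1 (0.53, adjusted p = 0.0859). Of 24 extracellular matrix genes, 7 rose and 0 fell (9 and 1 over the list alone), among them Timp1, Col6a1 (2.10), Col5a2 (1.07) and Col6a2 (1.41, and 0.36 in another probe set), with adjusted p = 0.00144, or 0.318 with an estimated correlation. With the filter at the 50th percentile the median of this list was -0.02 and its call ended (adjusted p = 0.143). Of 19 genes of hypoxia and glycolysis, 7 rose and 0 fell (7 and 0 over the list alone). Among them were the glucose transporter Slc2a1 (1.49), Ldha (1.10), Bnip3 (0.92) and Pdk1 (1.34, and 3.04 in another probe set). Camera gave this list adjusted p = 5.576e-06, or 0.323 with an estimated correlation, and its median was 0.74 (0.43 with the mean of a gene's probe sets). Of 18 p53 targets, 4 rose and 0 fell (4 and 0 over the list alone): the death receptor Fas (1.53), the cell cycle inhibitor Cdkn1a (2.33), Ccng1 (0.96) and Sesn2 (0.79), with adjusted p = 0.000962, or 0.372 with an estimated correlation, and a median of 0.46 (0.24 without heterozygous replicate 2). Of 24 G1/S genes, 3 rose and 0 fell (13 and 0 over the list alone), Fen1 (0.91), Pold1 (0.72) and Ccne1 (1.02). Of 29 G2/M genes, 1 rose, Mad2l1 (1.36), and 0 passed over the list alone, at a list median of 1.36 (0.73 without heterozygous replicate 1). Their camera adjusted p-values were 1.345e-08 and 2.139e-09, and 0.385 and 0.427 with an estimated correlation.

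Markers of glial states moved in both directions, in the same arrays in which macrophage markers were higher. Of 15 markers of oligodendrocyte progenitors, the cell state of PDGFB-driven gliomas, 6 fell and 0 rose (11 and 0 over the list alone), among them Rlbp1 (-1.76), the transcription factor Olig2 (-0.67 ± 0.13, SE, adjusted p = 0.0251), Ptprz1 (-0.61) and Cspg5 (-0.84). Of 21 proneural glioma genes, 7 fell and 0 rose (9 and 1 over the list alone), among them the Notch ligands Dll1 (-0.93) and Dll3 (-0.75), Marcks (-0.57) and Gpm6a (-0.60). Camera's adjusted p was 8.041e-06 and 0.00157, and 0.318 for both with an estimated correlation. The proneural median of -0.39 was -0.24 without wild type replicate 1. Of 20 astrocyte markers, 4 rose and 1 fell (6 and 1 over the list alone), with rises of Gfap (1.49), Sox9 (1.34) and Aldh1l1 (1.46). Of 18 neural stem cell markers, 6 rose and 1 fell (8 and 3 over the list alone), with rises of Id3 (1.96), Tnc (2.80) and Cd44 and a fall of Hes5 (-1.05, and -0.69 in another probe set). Camera gave adjusted p = 0.0228 and 0.0219, and 0.428 and 0.323 with an estimated correlation. The astrocyte call ended without wild type replicate 1 (adjusted p = 0.0656), without heterozygous replicate 2 (0.303) and with the filter at the 50th percentile (0.121), its median of 0.35 ran from 0.06 with that filter to 0.56 without heterozygous replicate 1, and the stem cell call ended without heterozygous replicate 1 (0.0669). Of 10 ependymal and choroid plexus markers, 2 rose, Foxj1 (1.71) and Rarres2 (1.97), and 0 fell (2 and 0 over the list alone), with adjusted p = 0.0261, or 0.534 with an estimated correlation. This call ended without wild type replicate 1 (adjusted p = 0.192), without heterozygous replicate 2 (0.0957), with the filter at the 50th percentile (0.0891), with shared probes left out (0.0616) and with the 3' minus 5' covariate (0.0709). Of 13 receptor tyrosine phosphatases outside the family of Ptprd, 6 fell, among them Ptprm (-0.79), Ptpro (-0.64) and Ptprk (-0.73, and -0.26 in another probe set), and the leukocyte gene Ptprc rose (9 and 1 over the list alone). The adjusted p was 0.00305, or 0.318 with an estimated correlation.

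Other lists were not called by camera in heterozygous against wild-type cells. The adjusted p was 0.0753 for type IIa receptor phosphatases and their partners (2 of 7 fell, Slitrk1 by 1.15 and Trio by 0.66, and 2 over the list alone), 0.0759 for neurons (3 of 12 fell, Gad1 by 1.24 among them, and 6 over the list alone), 0.0753 for granulocytes (1 of 5 rose, Lcn2, also over the list alone) and 0.161 for myelinating oligodendrocytes (0 of 15). It was 0.161 for immediate early and dissociation genes (5 rose and 1 fell of 24, with a rise of Zfp36 by 1.35 and a fall of Klf2 by 1.02, and 5 and 2 over the list alone), 0.313 for PDGF feedback genes (2 rose and 3 fell of 18, and 2 and 8 over the list alone), 0.313 for T, B and NK cells (0 of 7), 0.499 for endothelium and pericytes (1 of 13 rose, Tagln by 1.58, also over the list alone) and 0.933 for cytokines (Tgfb3 fell by 0.85, of 9, and 1 rose and 2 fell over the list alone). For myelinating oligodendrocytes and for T, B and NK cells the count over the list alone was 0. The median of the cytokine list was -0.03, while its mean and camera's direction were above 0. Among lists with too few measured members for a set test, 0 of 3 red blood cell genes, 0 of 4 genes at the Cdkn2a locus and 0 of 4 sex-linked genes passed the threshold. Of 28 lists tested, camera called 17 at the preset correlation and 0 with an estimated correlation. Fry, which tests whether the genes of a list move on balance in a common direction, called 9.

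**Figure D3:**
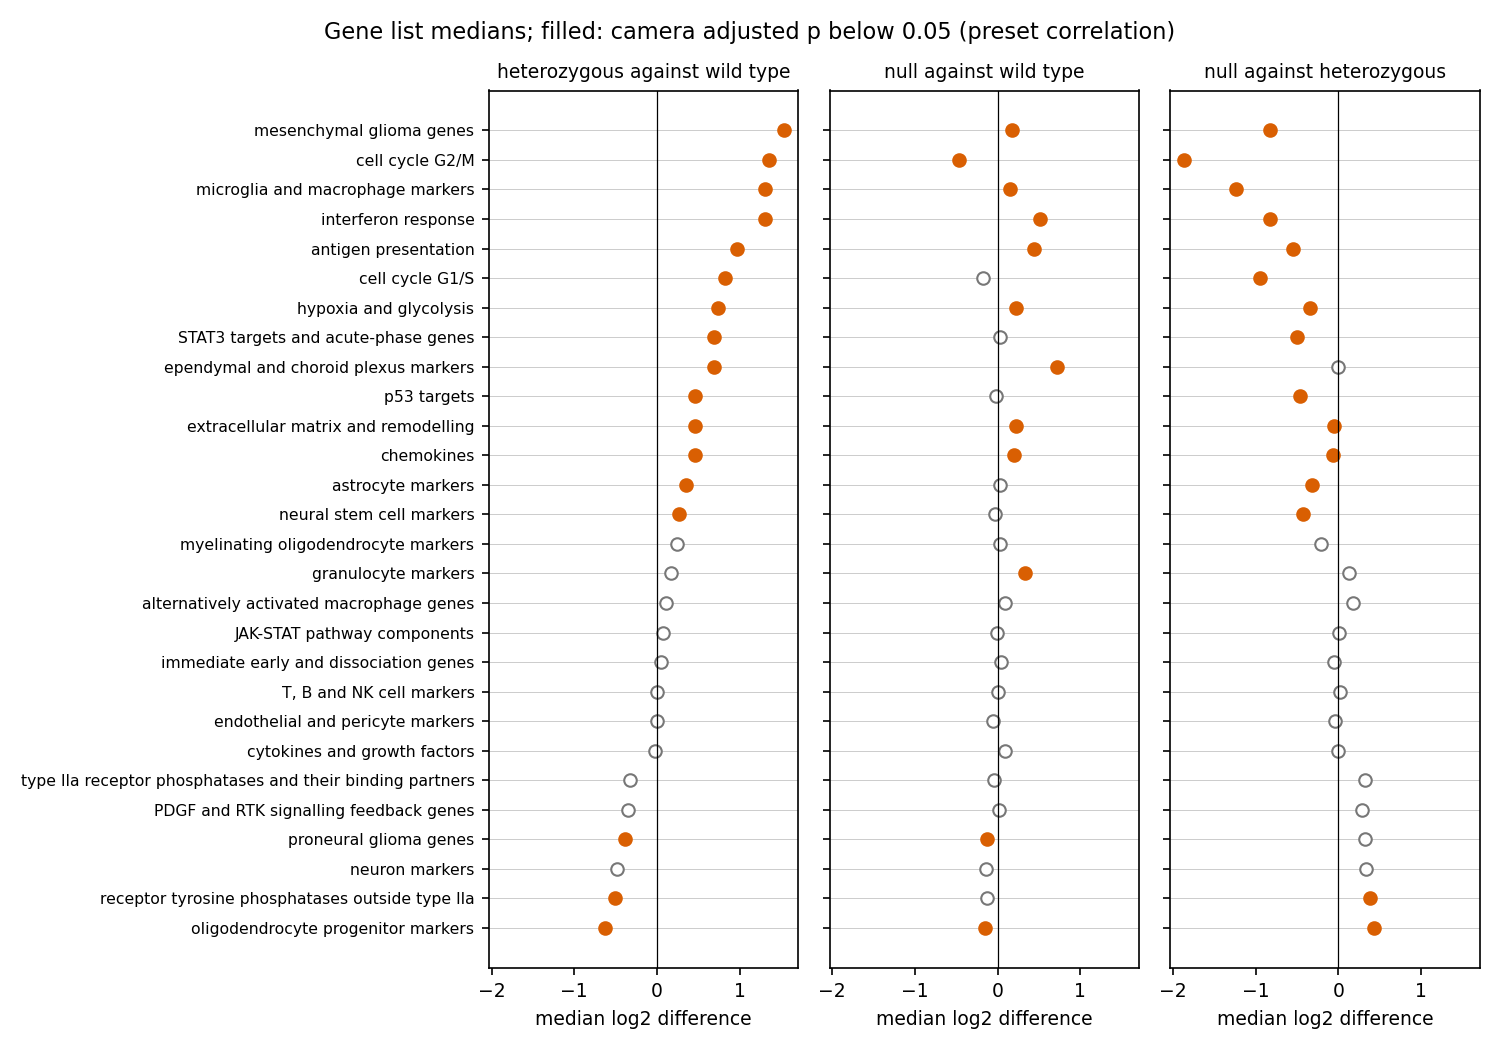
Median log2 difference (x axis) of the 28 gene lists tested (y axis) in the 3 pairs of genotypes, with filled points where camera with the preset correlation gave an adjusted p below 0.05. The mesenchymal list has a median of 1.54 in heterozygous against wild type, 0.17 in null against wild type and -0.83 in null against heterozygous (-0.45 without a filter and -1.77 with the filter at the 50th percentile), and 0 lists pass with an estimated correlation.

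In null against wild-type cells no gene passed the threshold with limma (0 of 9243, smallest adjusted p = 0.883), and 475 genes had an unadjusted p under 0.05 where 462.2 would by chance. This comparison asks how glioma cells differ after loss of both alleles. The smallest p-values among higher genes were those of Pdk1, a kinase that holds back pyruvate oxidation (log2 difference 1.09 ± 0.17, SE), and Anxa1 (0.81 ± 0.13). The other probe set of Pdk1 differed by 2.32, so the size of its difference is uncertain. Afm (0.72), Anxa2 (0.59), Olfml3 (0.76), Plekhg6 (0.45), Metap1d (1.19), the cystine transporter Slc7a11 (0.48), Tmem119 (0.48) and Tcl1b3 (0.49) followed. On the lower side stood Lrp1b (-0.93 ± 0.15), Ptprd, Rlbp1 (-0.86), the calcium channel Ryr2 (-0.79), Sema5a (-0.64), Sh3rf1 (-0.48), Prss23 (-0.81), Slc25a13 (-0.45), Ralgapa1 (-0.67) and Zfp60 (-0.51). Each of these genes had an adjusted p of 0.883. The groups did not overlap for 21.7% of genes, against 20% by chance. Camera called 12 lists at the preset correlation, although no member passed the gene test over all genes. With an estimated correlation camera called 0 lists (smallest adjusted p = 0.485), and fry called 0. Medians were above 0 for ependymal and choroid plexus markers (0.72), interferon response (0.51), antigen presentation (0.44), granulocytes (0.34), hypoxia and glycolysis (0.22), extracellular matrix (0.22), chemokines (0.19), mesenchymal genes (0.17) and macrophages (0.15), and below 0 for G2/M (-0.47), oligodendrocyte progenitors (-0.16) and proneural genes (-0.12). Of the 12 calls at the preset correlation, those of interferon response (median 0.03), antigen presentation (-0.04), G2/M (-0.11) and ependymal markers (0.37) ended without wild type replicate 1. Without wild type replicate 2, those of macrophages (-0.01), oligodendrocyte progenitors (-0.05), mesenchymal genes (0.11), extracellular matrix (0.16) and granulocytes (0.26) ended. Leaving out null replicate 1 ended the calls of ependymal markers (0.29) and antigen presentation (0.41), null replicate 2 those of macrophages (0.03), progenitors (-0.19), hypoxia (0.12) and antigen presentation (0.24), and null replicate 3 that of G2/M (-0.26). Medians were over 1.5 times larger without wild type replicate 2 for interferon response (1.00), antigen presentation (0.82) and G2/M (-0.77), and without null replicate 2 for G2/M (-0.85). They were also that much larger without wild type replicate 1 for macrophages (0.33), mesenchymal genes (0.26), extracellular matrix (0.33) and granulocytes (0.56), without null replicate 1 for macrophages (0.26) and mesenchymal genes (0.25), and without null replicate 3 for macrophages (0.23) and antigen presentation (0.68). The call of antigen presentation ended in 5 other settings (adjusted p between 0.0668 and 0.139, arrays left out aside), that of granulocytes with repeated quantile normalization (0.0539) and that of extracellular matrix without a filter (0.0624) and with the filter at the 50th percentile (0.241). The calls of chemokines and proneural genes held with each array left out. Adjusted over the list alone, 2 mesenchymal, 2 macrophage, 1 hypoxia and 1 cytokine gene were higher and 1 progenitor gene was lower. Median and mean differed in sign for JAK-STAT components and for immediate early genes, neither of them called. Another tool setting gave 1 gene in 3 cases, each named after its value was seen: the mean of a gene's probe sets called Pnpt1, the unmoderated model called Zfp2, and the fit without null replicate 1 called S100a8.

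This comparison asks what loss of the remaining allele adds. Tacr3 was higher in null cells by 3.53 ± 0.35 (log2, SE, adjusted p = 0.00539), Meox1 by 2.72, Aldh1a1 and Pcdhb9 by 2.53, and Cntn3 by 2.08. Otos (1.91), Pcp4 (1.87), Slc7a10 (1.86), Rit2 (1.72) and Folh1 (1.63) were also higher. Clca3a1 (-5.55), Cd44 (-5.07), Lcn2 (-4.44), Aldh1a3 (-4.21), Moxd1 (-4.10), Hpgd (-3.91), Timp1 (-3.69 ± 0.18, adjusted p = 0.000739), Osmr (-3.57), S100a10 (-3.27) and Cacng5 (-3.16) were lower. The null mean of Timp1 lay below the 30th percentile of each null array (4.86 to 4.95). Its difference is therefore taken against a dim level, and its exact size is uncertain. Other probe sets gave -2.27 for Cd44 and -0.18 for Csf1r, and a smaller difference for Aldh1a3. Csf1r was lower by 1.23 ± 0.21 (log2 difference -1.23, adjusted p = 0.0165), and 12 of 24 macrophage markers were lower (19 adjusted over the list alone). G2/M genes had a median log2 difference of -1.86, with 11 of 29 lower (28 over the list alone), and a median of -1.21 without heterozygous replicate 1. Camera's adjusted p was 8.968e-13 and 5.021e-15, or 0.336 and 0.398 with an estimated correlation. Camera called 15 lists, 2 up and 13 down, with an estimated correlation 0 (smallest adjusted p = 0.303), and fry called 9. In all, 828 genes passed, 462 higher and 366 lower. Of these, 608 were also past the threshold in heterozygous against wild type, all with the heterozygous cells apart in the same direction (255 with heterozygous higher and 353 with heterozygous lower). Both comparisons share the heterozygous arrays, which favours such an overlap. Across genes, the covariance of the differences of heterozygous from wild-type and from null cells was 0.229, against 0.0204 in simulations of unchanged groups that share the heterozygous arrays, and the correlation was 0.920 against 0.549. Whether higher or lower genes were in excess also depended on the setting, with 666 higher and 353 lower in arrays centred on their medians and 345 and 387 without null replicate 2. The count was 355 without wild type replicate 1 (188 higher and 167 lower), the same without wild type replicate 2, 90 without heterozygous replicate 1 (24 and 66), 290 without null replicate 1 (152 and 138), 205 without null replicate 3 (105 and 100), 2 without moderation (Svil and Zfp2, named after their values were seen), 355 with these groups alone, 471 with the 3' minus 5' covariate (231 and 240), 482 with array weights (271 and 211), 1279 with the Y-linked covariate (716 and 563) and 0 (1426 at an unadjusted limma p under 0.05) without both arrays that carried Xist and Y-linked transcripts.

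When heterozygous and null cells were averaged and set against wild type, 30 genes passed, 18 higher and 12 lower. Anxa2 was higher by 1.67 ± 0.10 (log2, SE, adjusted p = 0.00753), Timp1 by 2.09 (against a dim wild-type level) and Anxa1 by 1.40. In null against wild-type cells 0 of these passed. The count was 236 with array weights (117 higher and 119 lower), 55 with a trend and robust moderation (31 and 24), 47 with every probe set by itself (26 and 21), 46 with the Y-linked covariate (26 and 20, a setting chosen after the data were seen), 10 without moderation (3 and 7) and 3 with the 3' minus 5' covariate (3 and 0). The genes that passed with an array left out were named after their values were seen: Col4a5 without wild type replicate 1, 0 genes without wild type replicate 2 (826 at an unadjusted limma p under 0.05), 5 without heterozygous replicate 1 (Anxa2, Cd53, Lcn2, Tgm1 and Timp1), Timp1 without heterozygous replicate 2, 0 without null replicate 1 (1567), and Anxa2 and Lgals3 without null replicate 3. The F test over the 3 genotypes called 522 genes, of which 504 were also called in heterozygous against wild type. Its smallest p-values were for Anxa2, Timp1, Gadd45g, Tgm1 and Cd109. It called 161 genes without wild type replicate 1, 99 without wild type replicate 2, 34 without heterozygous replicate 1, 142 without heterozygous replicate 2, 266 without null replicate 1 and 229 without null replicate 3, and 821 with a trend and robust moderation, 949 with the Y-linked covariate, 21 without moderation and 217 with the 3' minus 5' covariate. Both counts were 0 without the 2 arrays that carried Xist and Y-linked transcripts (1359 and 1338 genes at an unadjusted limma p under 0.05). A slope on the number of wild-type alleles called 0 genes with limma, and 170 had an unadjusted p under 0.05 where 462.2 would by chance. The slope fit counts the distance of the heterozygous arrays from a straight line as spread, so it says little about a graded change. The genes of smallest p were Afm (0.35 per allele lost), Slc25a13 (-0.23), Slc7a11 (0.23), Zfp60 (-0.25) and Zbtb3 (0.25).

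Differences from wild type in heterozygous and in null cells were then compared gene by gene. Both comparisons share the wild-type arrays, and the differences had the same sign for 65.2% of genes, against 68.4% in simulations of unchanged groups that share these arrays. The covariance of the 2 differences across genes was 0.0351, against a mean of 0.0206 in those simulations (0.01745 to 0.02595), and the correlation was 0.339 against 0.552. The simulated heterozygous group was unchanged, whereas 938 genes passed in the data. Changes in heterozygous cells alone lower the share of equal signs and the correlation. These 2 measures therefore do not show how far the effects in heterozygous and null cells agree. With a different wild-type array for each comparison the covariance was 0.0342 in 1 pairing and -0.0127 in the other. Without wild type replicate 1 it was 0.0739.

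**Figure D4:**
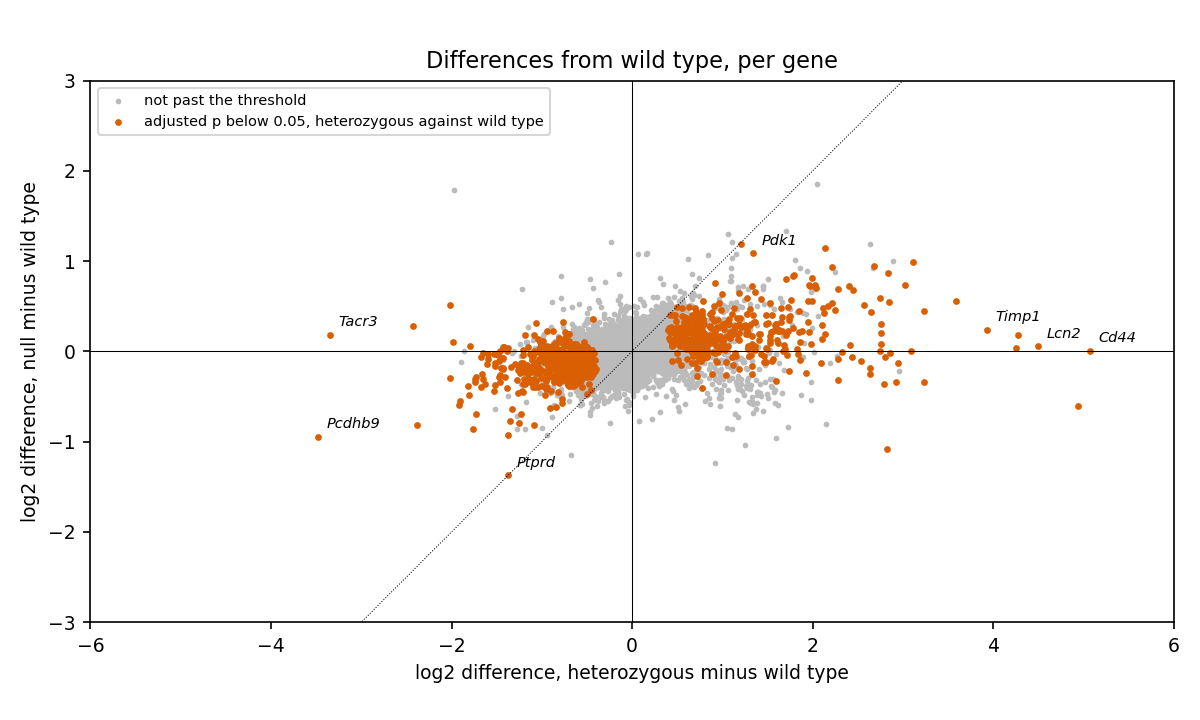
Log2 difference from wild type of each of 9243 genes in heterozygous (x axis) and null (y axis) cells, with the genes past the threshold in heterozygous against wild type in orange and the line of equal differences dotted. Cd44 lies at 5.08 and 0.01, and Ptprd lies on the line at -1.37.

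Ptprd lies on chromosome 4 (GRCm38.p6), and because of the mixed background the DNA around it can differ in strain between genotypes. Of the 100 genes of smallest p in null against wild-type cells, Ptprd left out, 0 lay within 20 Mb of Ptprd, where 63 of the tested genes lie and 0.682 would be expected among 100 (odds ratio 0, upper 95% limit 5.57, Fisher's exact p = 1). Without null replicate 2 the odds ratio was 1.48.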

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

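Of the tests below, those on macrophage markers (for rises and for falls) and on RNA quality were worded after related results had been seen, and the condition on the spread in the test of digestion was added after its value was seen. The macrophage explanation was first written as a single prediction, and it was parted into rises and falls, with its bounds reworded, once the median of the list was known. As first written, the falls would have counted against it.

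A signal in data outside the named genes was found among the 1293 probe sets that name no gene or several genes. With limma, 96 of them passed the threshold in heterozygous against wild-type cells, 64 higher and 32 lower, 0 in null against wild type and 39 in null against heterozygous. Among named genes 938 of 9243 passed in heterozygous against wild type, a larger share, so these probe sets do not stand out from the named genes. The Affymetrix control RNAs added at hybridisation, which contain no mouse RNA, were higher in heterozygous than in wild-type arrays by 0.278 on the log2 scale (11.2 and 11.3 against 10.97 and 10.96, with 10.6 to 11.1 in null arrays). Whether the difference in these control RNAs exceeds chance was not tested.

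The heterozygous arrays stand apart from wild type and null, although the null cells have lost both alleles. The tables argue against RNA quality only as far as the 3' minus 5' difference of the control transcripts measures it. For this difference, 2 of 2 heterozygous arrays lay within the range of the other 5 (0.747 and 0.896, range 0.615 to 0.906). With it as a covariate 372 genes passed, against 938 without it, so the fit with the covariate does not decide the question. The tables also argue against sex, since 3 wild-type or null arrays had sex-linked transcripts of the same kind as a heterozygous array. Myeloid cells that passed the sort on the fluorescent marker stay open, both for the macrophage markers, where the median of 1.43 over the 10 brightest restates that all 24 measured markers were higher and so decides nothing, and for the falls: a fall of 1 needs 50% foreign RNA, 122 genes fell further than that, and the 10 brightest markers had a median percentile of only 59.2 and 63.6 on the heterozygous arrays, but how bright they are in myeloid cells was not measured. Tissue digestion and chance stay open: the immediate early and dissociation list had a median of 0.0483, under the bound of 0.25 set against digestion, but with an SD of 0.865 over members that went both ways (13 of 24 higher) it decides nothing, and 5 of 100 splits of the arrays into groups of 2, 2 and 3, the real grouping included, gave at least the 522 genes of the F test (highest other 1087), so chance is not excluded. All of those 5 keep the heterozygous pair together, and splits that part it gave at most 4 genes, so the F count follows a structure of the samples, and an effect of the genotype, of the stage at which tumours were taken and of any unrecorded batch of these 2 arrays stay open and untested.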

How the results depend on the processing

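The fits without the 2 arrays with both Xist and Y-linked transcripts and with the Y-linked level as a covariate were chosen after the data were seen. Repeated quantile normalization, median centring, probe sets with shared probes left out and sex-linked genes left out kept every count of genes within 1.5 times of that reported. The cause was not tested where none is named.

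Counts are given for heterozygous against wild type (938 as reported), null against heterozygous (828), deficient against wild type (30) and the F test (522), in that order where several stand. Every probe set by itself gave 47 for deficient against wild type, and moderation with a trend gave 55 and, for the F test, 821. Without moderation, which leaves 4 residual degrees of freedom, the counts were 97, 2, 10 and 21, with 1 for null against wild type, as with the mean of all probe sets (1). Array weights gave 482 for null against heterozygous and 236 for deficient against wild type. With only the 2 groups compared, on fewer arrays, 172 and 355 genes passed. The 3' minus 5' covariate gave 372, 471, 3 (Anxa1, Anxa2 and Timp1) and 217. Without the 2 arrays with both Xist and Y-linked transcripts each count was 0, with 1 heterozygous array left, and with the Y-linked level as a covariate the last 3 counts were 1279, 46 and 949. With the replicate block the counts were 217, 25, 0 and 29. Same-numbered arrays did not deviate together throughout (correlations of replicate 1 minus 2 across genes of 0.111, -0.348 and -0.106), so the number gives no sign of a pairing. At -0.348, same-numbered wild-type and null arrays deviated in opposite directions, and wild type replicate 1 correlated best with null replicate 2 (0.995).

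Leaving out each array in turn, with a lone array assumed to vary like the other groups, gave 33 to 802 genes for heterozygous against wild type, 0 to 1 for null against wild type, 90 to 732 for null against heterozygous, 0 to 22 for deficient against wild type, 34 to 470 for the F test and 0 to 0 for the slope. Ptprd in null against wild type ranged from -1.588 to -1.102, the covariance of both differences from 0.02527 to 0.07385, and the odds ratio near Ptprd from 0 to 1.478. The covariance was 0.03025 without a filter, 0.04658 with the replicate block, 0.02991 with the Y-linked covariate and -0.01271 for heterozygous against wild type 2 with null against wild type 1. The odds ratio was 1.384 with the filter at the 50th percentile and 1.433 with the mean of all probe sets.

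The median of the extracellular matrix list turned in heterozygous against wild type with the 50th percentile filter (-0.01721), and in null against heterozygous with that filter (0.06442), the mean of all probe sets (0.0233), the 3' minus 5' covariate (0.007412) and without null replicate 2. With arrays left out in turn, that median ran from -0.2456 to 0.0534. In null against wild type, leave-one-out medians ran from -0.03762 to 0.8157 for antigen presentation and -0.1177 to 0.1805 for immediate early genes (lowest without wild type replicate 1), -0.01217 to 0.3296 for macrophage markers (lowest without wild type replicate 2) and -0.1425 to 0.1457 for myelinating oligodendrocytes (lowest without null replicate 1, and also -0.1425 without both arrays with Xist and Y-linked transcripts). Camera called 14 to 18 lists in heterozygous against wild type under the other settings of array, filter, probe set and covariate, 17 with macrophage genes left out of other lists, 9 with fry and 0 with an estimated correlation. Only 2 tested macrophage markers (Ptprc, Cd74) stand in another list, so leaving them out could change little and decides nothing about myeloid cells. Signs and calls were followed for Ptprd, the named rises and falls of each pair of genotypes, the slope genes and those chosen by name. No called gene among these turned its sign. Genes named only for their gene list or the F test were not followed. With every probe set by itself, only a gene's brightest probe set was followed. Among the followed genes past the threshold in heterozygous against wild type, 131 results over all settings lost the call and 437 kept it. In null against heterozygous 131 lost it and 416 kept it. Signal over background limits the dim genes, of which 3150 were not tested.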

Other observations

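Of the tests in this part, those on the mixed sex-linked transcripts and on the neighbours of Pdk1 were chosen after the result was seen, and the condition on the upper limit in the test around Ptprd was added after its value was seen.

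Xist and Y-linked transcripts in heterozygous replicate 1 and null replicate 1 were set against arrays that carried only 1 kind. Relative to those arrays, Xist stood at 0.261 and 0.842 and the Y-linked genes at 0.588 and 0.401, so the shares added up to 0.849 and 1.243. A single mouse with 2 X chromosomes and a Y would carry each near a share of 1, and the sums, at most 1.243, are below the 1.6 that this needs. Material of mice of both sexes in 1 sample is a candidate explanation, since it predicts sums near 1. The sum of 1.243 in null replicate 1 lies above the 0.804 to 1.18 of the arrays of a single kind, which set the scale and so are near 1 by construction. No other biological explanation was tested.

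Genes close together on a chromosome were examined because the strain background is mixed. Pdk1 and Metap1d, both among the 10 named genes with higher values in null cells, are neighbours on chromosome 2. With both left out, 3 of 36 tested genes within 5 Mb of Pdk1 had an unadjusted limma p under 0.05 in null against wild type (8.33%, against 5.11% of other genes, Fisher's exact p = 0.43), so a block of strain DNA cannot be told apart from chance with so few neighbours. Around Ptprd on chromosome 4 the odds ratio was 0, with an upper limit of 5.57, because 0.682 genes were expected, so although an odds ratio of at most 1 had been set against strain DNA linked to Ptprd, it decides nothing and this stays open as well.

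Of the 24 macrophage markers, 18 had a wild-type mean above the filter percentile and 2 (Ptprc, Cd74) also stand in another list. Spike controls that are added before labelling were lower in null replicate 2 (9.14) than in the other arrays (10.4 to 11.2).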
